A study of Homo sapiens with 4 samples.

How the data were processed

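Frozen sarcoma specimens were sectioned onto Visium slides and sequenced, per the labels' protocols, which give 3 sections of undifferentiated pleomorphic sarcoma (UPS) and 1 of leiomyosarcoma (LMS). Replicates were numbered within a tumour type, and the numbers pair no samples. The authors deposited, for each section, a matrix of raw UMI counts per gene and array spot, with whole numbers, totals that differ between sections and no normalization. The counts were made with Space Ranger 1.3.0 against GRCh38, per the submitters' processing notes; the annotation release and how tissue was marked are not given in the sources used here. Each matrix holds 36601 genes and all 4992 array spots, tissue or not, and a positions table marks tissue spots and gives array rows and columns. The images and their scale factors were not used here.

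Gene symbols and Ensembl IDs were taken from the files, and 36366 of the 36601 IDs matched a gene name table. Coordinates are from the RefSeq genes of GRCh38.p14, matched on symbol, for 216 of 219 named genes. Genes on chromosome Y, XIST and TSIX (113 in all) were left out of every test. Choices of tests, designs, lists, named genes and most alternatives were made before the data were examined; alternatives on the tissue mask, and those that leave out sections from list tests, were chosen after seeing the data.

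Tissue spots with at least 500 UMIs were kept. The depth of the kept spots was 2796945 UMIs in LMS 1, 4554397 in UPS 1, 6876232 in UPS 2 and 578651 in UPS 3. Counts were summed per section, and the LMS section was tested against the 3 UPS sections with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The spread comes from the UPS sections alone, with 2 residual degrees of freedom, and the lone LMS section is assumed to vary like them. CPM values use TMM-scaled totals for genes, and plain totals for lists with 95% exact Poisson intervals that cover counting error only. Where a group had no count, a floor of 3 counts over the group bounds the fold. P-values and SEs of edgeR rest on a spread between these sections that is moderated over genes. The sections of 1 gene can therefore differ by more than its SE tells. Camera p-values compare the genes of a list with the other genes. That each section came from another person is not stated in the labels.

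A total of 28 lists were fixed, 18 of cell types and 10 of programs, with 290 genes, none held by more than 1 list. Cell type lists were T cell, cytotoxic lymphocyte, B cell, plasma cell, macrophage, lipid-handling macrophage, neutrophil, dendritic cell, mast cell, endothelial, pericyte, smooth muscle, fibroblast and matrix, adipocyte, skeletal muscle, erythrocyte, epithelial and Schwann cell. Program lists were hypoxia, proliferation, interferon response, class I and class II antigen presentation, immune checkpoint, lymphoid aggregate chemokine, TGF-beta response, immediate early and heat shock, and matrix remodelling enzyme. Lists were tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and again with an estimated correlation.

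For regions, a spot's list score was the mean of z-scored log1p counts per 10000 UMIs over list genes detected in at least 1% of the spots. Within each of 10 depth bins the 20% of spots with the highest score formed the region, and the summed region was tested against the summed rest with edgeR, section as block, on 4 sections. Pairs of lists were compared by Spearman correlation across spots with log depth removed on ranks, for lists with at least 3 detected genes, and against 1000 random lists matched on expression. Moran's I used the 6 nearest array neighbours. Spots are not replicates, and no p-value was taken from spots. Random lists and other splits of the region sums used fixed seeds, with 20 random lists per region test. Versions were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

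Named genes followed a fixed rule. For LMS against UPS these were up to 12 genes per direction past the test with a mean of at least 10 CPM and an LMS value outside the UPS range, filled to 5 with the largest fold changes that did not pass. For regions they were the 12 largest changes per direction with an adjusted p under 0.05, a mean of at least 20 CPM and the same sign in all 4 sections. Up to 4 members of each called list, the 8 highest and 8 lowest like-signed pairs, up to 25 shared spatial genes with the 5 highest of each section, and the 5 genes of highest outside share per section were also named. Y-linked genes, XIST, TSIX, genes that follow common inherited deletions or haplotypes, V, D and J segments, mitochondrial and ribosomal protein genes and clone-named features were never named.

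Scripts were tested on simulated data. With counts drawn from the pooled means and the library sizes of the sections for 14706 genes, the LMS against UPS step of edgeR recovered 2.99% of genes changed 4-fold, 58.2% at 16-fold and 83.3% at 64-fold, with 23 false among 119 calls; DESeq2 recovered 5.97%, 74.6% and 89.4% with 77 false among 190. For region sums (11950 genes) edgeR recovered 44.8%, 85.1% and 100% at 1.5-fold, 2-fold and 4-fold with 4 false among 157 calls. DESeq2 recovered 16.4%, 61.2% and 92.4% with 0 false among 113. Genes were drawn independently there and no spots were chosen by a score. These counts of false calls therefore do not carry over to regions chosen by a list. Camera with an estimated correlation gave p = 0.00679 and p = 0.000524 for a changed list in these simulations. Simulated spatial gradients placed 64.5% to 93.0% of patterned genes among the 200 highest.

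Alternatives were RLE and plain library size scaling, DESeq2, no filter on low genes, other spot minimums, removal of mitochondrial, ribosomal and immunoglobulin genes, thinning to the smallest section, other region shares (10% and 30% of spots), no depth balance, list share as score, no section block, Pearson correlation, neighbouring spots, 18 neighbours, Pearson residuals, other tissue masks, and leaving out each section in turn.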

Results

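Spatial gene expression was measured in 4 sections of human soft tissue sarcoma with Visium arrays, on which each spot captures polyadenylated RNA from a small area that can hold several cells. Undifferentiated pleomorphic sarcoma (UPS), a tumour without a recognisable line of differentiation, gave 3 sections, and leiomyosarcoma (LMS), a tumour with smooth muscle features, gave 1. Every section is named by its tumour type and a number, and no other replicate of LMS was analysed here. The questions implied by the design were how the LMS section differed from the UPS sections, and how gene expression was arranged within each section.

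Depth differed widely between the sections. UPS 2 held 7535061 unique molecular identifiers (UMIs), UPS 1 held 5149952, LMS 1 held 4202123 and UPS 3 held 2020724. The positions marked 2179, 1648, 2103 and 1446 spots as tissue, in the same order. The median tissue spot held 2960 UMIs in UPS 2, 2768 in UPS 1, 866 in LMS 1 and 258 in UPS 3. Tissue spots with at least 500 UMIs were kept, which left 2085 spots in UPS 2, 1597 in UPS 1, 1239 in LMS 1 and 400 in UPS 3. UPS 3 therefore rested on 578651 UMIs, against 2796945 to 6876232 in the other sections, and its values are the least precise. Across genes, log2 counts scaled to a common total (CPM) of any 2 sections correlated with Pearson's r between 0.614 and 0.746, where genes are not independent replicates.

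A large share of the RNA lay outside the area marked as tissue. This share was 60.9% in UPS 3, 29.5% in LMS 1, 11.2% in UPS 1 and 8.30% in UPS 2. In UPS 3 the first ring of spots outside the marked area held a median of 1259 UMIs, above the 808 of the tissue spots that touched the edge and the 199 of tissue spots further in. The ring in LMS 1 held 504.5 UMIs against 489 in its edge tissue, while the rings of UPS 1 and UPS 2 held 757 against 2911 and 359 against 2347.5. The summed profile of outside spots correlated with that of tissue with r between 0.938 and 0.959 across genes. PLCG2, a phospholipase C of immune cell signalling, had 89.5% of its counts outside the tissue in LMS 1, 90.7% in UPS 1, 46.3% in UPS 2 and 85.4% in UPS 3. MTRNR2L12 and MTRNR2L8, nuclear copies of the mitochondrial 16S ribosomal RNA gene whose reads can be shared with that gene, had 73.4% and 71.5% outside in LMS 1, 83.8% and 79.8% in UPS 1, 37.0% and 32.3% in UPS 2, and 91.8% and 89.7% in UPS 3. Other genes with a high outside share were MTRNR2L1 in LMS 1 (50.9%) and UPS 1 (62.5%), and PRG4, which encodes a joint lubricant, in LMS 1 (47.5%). The others were AOAH in UPS 1 (25.3%), HBB and PLIN1 in UPS 2 (28.2% and 25.2%), and IGLC1 and HCST in UPS 3 (82.5% and 73.6%).

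**Figure D1:**
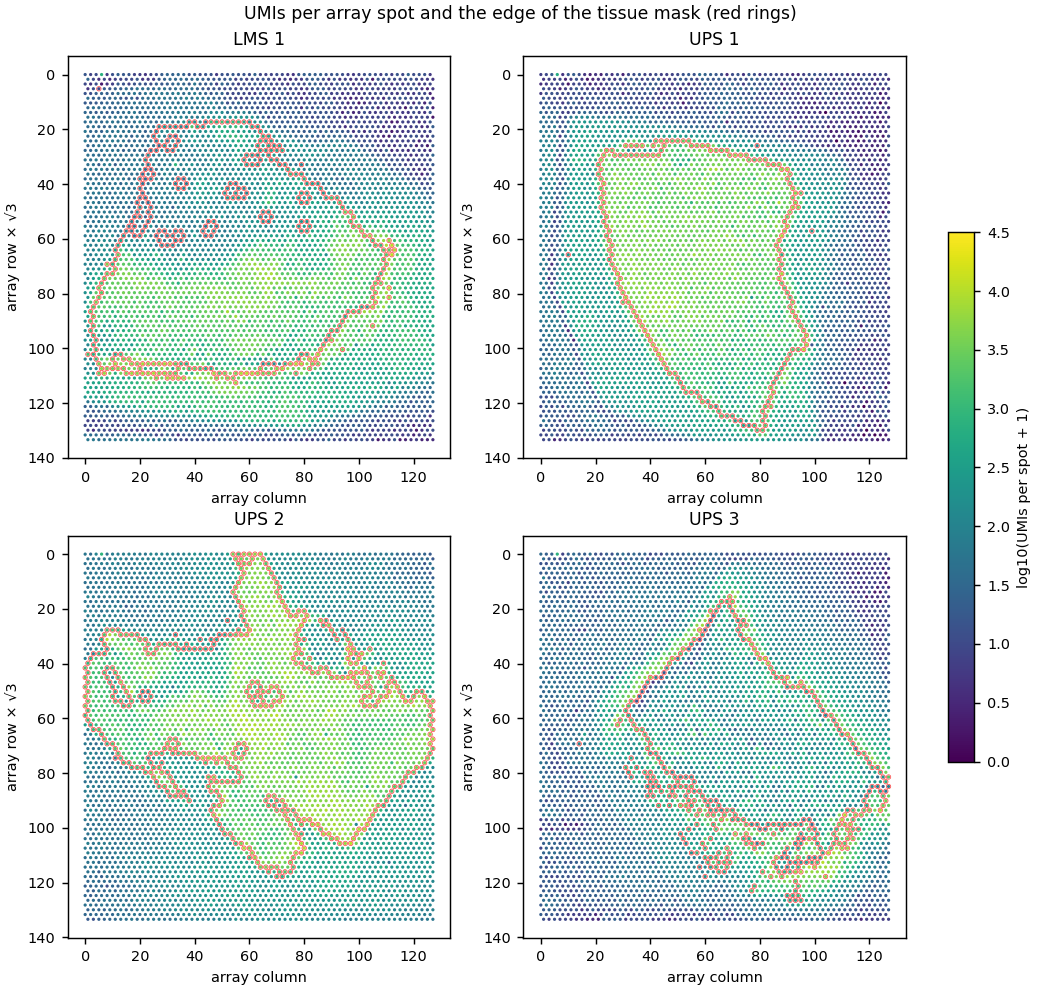
Each panel shows 1 section with all array spots at their array column and row (the row is stretched so that distances are to scale), coloured by log10 of the UMIs per spot plus 1; red rings mark tissue spots at the edge of the marked area. In UPS 3 the brightest spots follow the edge and lie partly outside it, where 60.9% of the UMIs were found.

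The LMS section carried far more RNA of smooth muscle contractile genes than the UPS sections. MYH11, the smooth muscle myosin heavy chain (ENSG00000133392, chromosome 16, 15703135 to 15857028 of GRCh38), stood at 1316 CPM in LMS 1 against 5.48 ± 4.79 CPM in UPS (SD, n = 3). ACTA2, the smooth muscle actin, stood at 6534 against 94.8 ± 58.4 CPM, MYLK, the kinase that starts smooth muscle contraction, at 1028 against 34.3 ± 11.8, and LMOD1, an actin filament nucleator of smooth muscle, at 475 against 5.42 ± 3.57. Together the 14 genes of the smooth muscle list made 18882 CPM in LMS 1 and 1347 ± 1096 CPM in UPS, a 14.0-fold difference. Pericyte genes were also above every UPS section, at 1250 against 450 ± 181 CPM, with MCAM, an adhesion molecule of vessel walls, at 434 against 31.4 ± 23.2 and CSPG4 at 201 against 36.0 ± 21. KCNJ8 and ABCC9, which form a potassium channel of mural cells, stood at 44.8 against 8.84 ± 8.09 and 61.8 against 21.5 ± 31.8 CPM.

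Immune genes were at much lower levels in the LMS section. The T cell list made 69.4 CPM in LMS 1 and 735 ± 419 CPM in UPS (SD, n = 3), and the cytotoxic lymphocyte list made 15.7 against 323 ± 171. CD3E, a chain of the T cell receptor complex, stood at 2.04 against 41.4 ± 19.4 CPM, LCK at 1.02 against 23.7 ± 7.73, CD8A at 0.339 against 81.6 ± 72.2 and TRBC1 at 3.73 against 100 ± 62.6. Of cytotoxic genes, GZMA stood at 1.36 against 47.0 ± 24.6, NKG7 at 4.41 against 84.6 ± 37.4 and PRF1 at 1.36 against 27.0 ± 15.3 CPM. GZMK had no count in LMS 1 against 56.3 ± 34.9, at least 55.3-fold lower on a floor of 3 counts per group. Plasma cell genes made 47.6 against 1551 ± 1439 CPM, with IGKC, the immunoglobulin kappa constant gene, at 5.77 against 618 ± 546, IGHG3 at 3.39 against 264 ± 220, IGHG1 at 1.02 against 108 ± 100 and IGLC2 at 0.339 against 288 ± 285. Chemokines of lymphoid aggregates made 8.94 against 133 ± 34.4 CPM. CXCL13, which attracts B cells, had no count in LMS 1 against 21.6 ± 13.3 CPM (at least 21.2-fold lower) and CCL21 none against 47.5 ± 36.6 (at least 46.7-fold lower), while CCL19 stood at 1.02 against 24.8 ± 17.0 and LTB at 6.11 against 28.6 ± 11.5.

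Macrophage and antigen presentation genes followed the same direction. The macrophage list made 569 CPM in LMS 1 and 4131 ± 1145 CPM in UPS (SD, n = 3). Its complement genes C1QA, C1QB and C1QC, made by tissue macrophages, stood at 129 against 988 ± 81.9, 65.8 against 1138 ± 522 and 32.2 against 347 ± 104 CPM, and MS4A7 at 6.45 against 99.6 ± 11.5. Class II antigen presentation made 955 against 6373 ± 2501 CPM, with HLA-DRA at 184 against 1670 ± 670, HLA-DPA1 at 59.4 against 838 ± 435, HLA-DPB1 at 70.3 against 664 ± 306 and HLA-DMB at 17.6 against 152 ± 64.6. Class I antigen presentation differed less, at 7622 against 10536 ± 2971 CPM, with TAP1, a peptide transporter subunit, at 34.6 against 174 ± 120, TAP2 at 19.7 against 61.1 ± 28.7, PSMB9 at 70.6 against 268 ± 189 and TAPBP at 122 against 306 ± 155. The interferon response list made 717 against 1970 ± 1397 CPM. CXCL9 and CXCL10, interferon-induced T cell attractants, stood at 0.679 against 119 ± 83.6 and 4.07 against 84.6 ± 52.9, and IFI27 at 127 against 692 ± 696. Immune checkpoint genes made 51.9 against 153 ± 90.8 CPM, where TIGIT, IDO1 and PDCD1 had no count in LMS 1 against 16.8 ± 8.03, 32.2 ± 32.5 and 16.7 ± 12.7 CPM (at least 16.5-fold, 31.6-fold and 16.4-fold lower) and HAVCR2 stood at 1.36 against 24.8 ± 9.30. Most of the 51.9 CPM in LMS 1 thus came from other members of the list, and 1 of its 10 members was higher there.

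Matrix genes were also lower in LMS 1, although the UPS sections differed strongly among themselves. The fibroblast and matrix list made 7097 CPM in LMS 1, 10067 in UPS 3, 22431 in UPS 1 and 61207 in UPS 2. DCN and LUM, small proteoglycans of collagen fibres, stood at 187 against 2154 ± 1815 and 170 against 1438 ± 1172 CPM (SD, n = 3), PDGFRA, a growth factor receptor of mesenchymal cells, at 3.05 against 529 ± 756 and THY1 at 84.2 against 876 ± 634. Matrix remodelling enzymes made 307 against 1316 ± 1294 CPM, with LOX, which crosslinks collagen, at 48.2 against 292 ± 254, MMP14 at 75.0 against 444 ± 450, CTSK at 30.2 against 347 ± 414 and ADAM12 at 20.03 against 160 ± 153.

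The test that compared LMS 1 with the 3 UPS sections called no single gene. edgeR's quasi-likelihood test covered 15490 genes and called 0 at an adjusted p of 0.05, with 1376 at an unadjusted p under 0.05, on 2 residual degrees of freedom and a biological coefficient of variation of 0.657 that came from the UPS sections alone. DESeq2 called 343 genes, 148 higher and 195 lower in LMS. The genes of largest fold change, none of which passed, were HOTAIR (238 counts in LMS 1, 80.8 CPM), EPPK1 (164 counts, 55.7 CPM) and KCNA5 (139 counts, 47.2 CPM), each with 0 counts in all UPS sections. This makes them at least 316-fold, 218-fold and 185-fold higher on a floor of 3 counts per group. HOTAIR, a long noncoding RNA of the HOXC cluster (ENSG00000228630), lies on chromosome 12 at 53962312 to 53974954. SBSPON had 520 counts in LMS 1 and 2 counts in UPS, and HAND2-AS1 had 177 and 1. In the other direction, LMS 1 held no count of FBN2, an elastic fibre protein (202 ± 158 CPM in UPS), MYH1, a skeletal muscle myosin (253 CPM), MGST1 (137 CPM), or the acute phase genes SAA1 (124 CPM) and SAA2 (64.9 CPM). FBN2 (chromosome 5, 128257909 to 128538245) was detected in each UPS section, at 384, 123 and 99.3 CPM, whereas MYH1 came almost wholly from UPS 2, at 755 CPM.

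Set tests over 27 of the 28 fixed lists (Schwann cell genes were too few) called 13 with camera at a preset correlation, and 0 with an estimated correlation. The smooth muscle list had an adjusted p of 6.57e-12 with 13 of its 14 members higher (adjusted p = 0.595 with an estimated correlation), and the pericyte list an adjusted p of 0.0357 (0.595 with an estimated correlation). Lower lists were macrophage (adjusted p = 4.77e-13), class II (6.82e-08), T cell (2.36e-07), fibroblast and matrix (5.25e-05), cytotoxic lymphocyte (6.12e-05), lymphoid aggregate chemokine (0.00345), immune checkpoint (0.00612), class I (0.00885), and plasma cell, interferon response and matrix remodelling enzyme (each 0.0357). For these the adjusted p with an estimated correlation was 0.595, or 0.632 for the plasma cell and interferon response lists. No list member passed among all genes. Adjusted over the list alone, 9 smooth muscle genes and 1 pericyte gene were higher in LMS, and 10 macrophage, 9 T cell, 5 cytotoxic, 4 plasma cell, 4 class II, 4 checkpoint, 3 chemokine and 2 interferon genes were lower. Counts of named lists aside, LMS 1 lay outside the range of the 3 UPS sections for 20 of the 28 lists, where chance gives 50% of lists, and the smallest one-sided exact permutation p that 1 section against 3 allows is 0.25. Without UPS 1, edgeR called 170 genes (136 higher and 34 lower) and camera 22 lists. Calls were lost for plasma cell (adjusted p = 0.159) and matrix remodelling enzyme genes (0.220) without UPS 2, and for interferon response (0.210) and class I genes (0.0662) without UPS 3. From spots inside the tissue edge the pericyte (0.287) and plasma cell lists (0.0671) were not called, nor were remodelling enzymes with the tissue mask ignored (0.108).

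**Figure D2:**
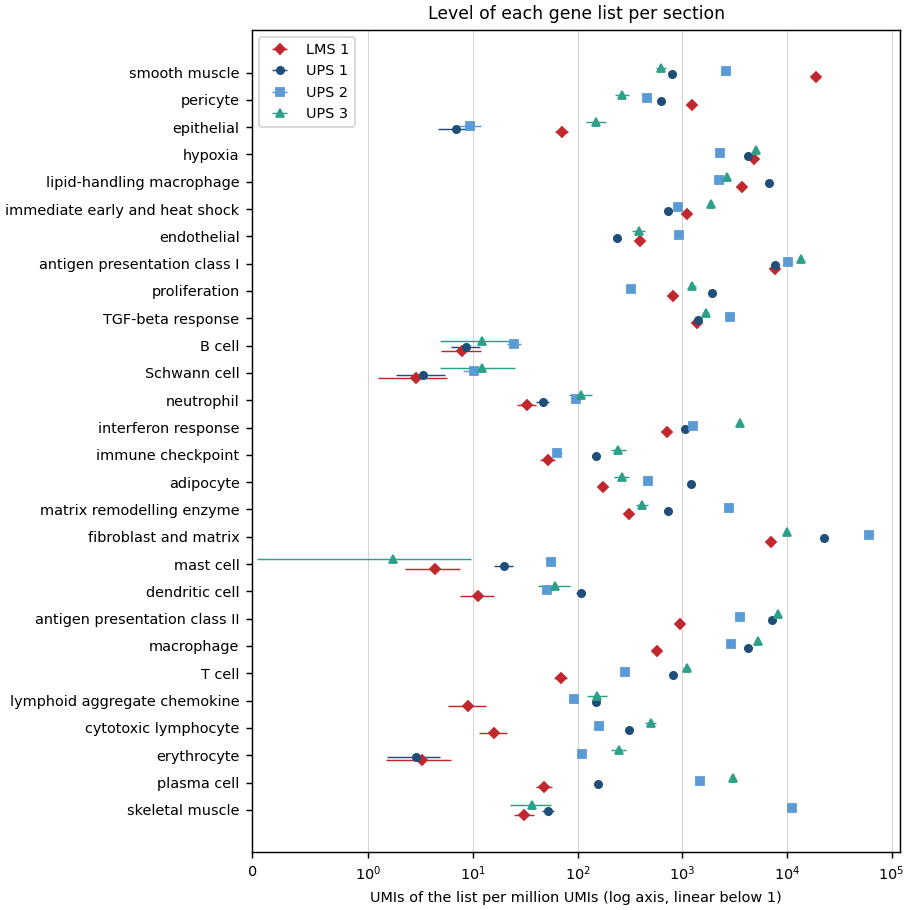
Level of each of the 28 gene lists in each section, as CPM on an axis that is logarithmic above 1 and linear below it; bars are 95% exact Poisson intervals, which cover counting error only. LMS 1 (red) lies above all UPS sections for smooth muscle and pericyte genes and below them for 18 lists, among them T cell, macrophage and class II genes.

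Within each section, regions were then defined by gene lists: the 20% of kept spots with the highest list score at matched depth were compared with the remaining kept spots of the same section, with the section as block. The genes of the choosing list were left out of each test, and the replicate is the section (n = 4), not the spot. Genes named for the largest changes had to share a direction in all 4 sections, so that shared direction is no result. The SE of a gene rests on a spread moderated over genes and can understate how its own sections differ. CCL19 in T cell regions had an SE of 0.20 and an SD between sections of 1.11. RGS5 in endothelial regions had an SE of 0.20 and an SD of 1.32.

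In T cell regions, genes that rose included those of chemokines and leukocyte surface proteins. PTGDS, a prostaglandin D2 synthase (ENSG00000107317, chromosome 9, 136977504 to 136981742), rose by a log2 fold change of 1.60 ± 0.19 (SE, n = 4; edgeR adjusted p = 5.36e-14), and CCL19, the chemokine that gathers T cells and dendritic cells (ENSG00000172724, chromosome 9, 34689570 to 34691276), rose by 1.45 ± 0.20 (adjusted p = 3.28e-10). Both were positive in all 4 sections, but CCL19 stood at 0.13 in UPS 1, had 3 UMIs each in LMS 1 and UPS 3, and without UPS 2 stood at 0.40 without passing. JCHAIN, the joining chain of secreted antibodies, rose by 1.23 ± 0.20, ITGAL, a leukocyte integrin, by 1.15 ± 0.20, and CD52, a lymphocyte surface protein, by 1.05 ± 0.14. Smaller rises that held in all 4 sections were those of TBC1D10C (0.97), TNFAIP3, an inhibitor of NF-kappaB signalling (0.93), IL2RG, the shared interleukin receptor chain (0.92), the chemokine CCL4 (0.88), CASP1 (0.87), ARHGAP9 (0.81) and GPSM3 (0.77). TSPAN18 (-0.98), FSTL3, an activin-binding protein (-0.81), FEM1B (-0.63), FAF2 (-0.61), TNFRSF12A, the TWEAK receptor (-0.53), and DPT, a matrix protein (-0.46), fell in all 4 sections, although FSTL3 and FAF2 lay within 0.01 of 0 in LMS 1. Of the 18 named genes 7 had fewer than 10 UMIs in at least 1 section, 6 of them in LMS 1, where their direction rests on few counts.

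In T cell regions, at least 1 member rose in each of 11 other lists. Of 8 tested plasma cell genes 7 rose, IGHG3 by 1.45 ± 0.11, IGHG1 by 1.31 ± 0.14, IGLC2 by 1.01 ± 0.12 and IGKC by 0.79 ± 0.10 (SE), but IGHG1 rose in 2 of 4 sections and IGLC2 in 1 of 4. Without UPS 2 the plasma cell list had a median of -0.09, with 4 of 8 genes positive (camera adjusted p = 0.973), and IGHG3 stood at 0.63, IGKC at 0.12, IGHG1 at -0.47 and IGLC2 at -1.04, none passing. CXCL9 and CXCL10 rose by 1.09 ± 0.13 and 1.17 ± 0.15, while IFITM1 (0.35) did not pass. GZMK rose by 0.96, NKG7 by 0.71, GZMB by 1.39 and CST7 by 0.90, which made 4 of 10 cytotoxic genes, and 8 adjusted over the list alone. CXCL13 rose by 1.70, LTB by 1.13 and CCL19 as above (3 of 6 lymphoid aggregate genes). IDO1 rose by 1.5 among checkpoint genes, with TIGIT (1.12), LAG3 (0.47) and PDCD1 (0.72) not passing. IRF8 rose by 0.63 among dendritic cell genes, with LAMP3 (1.78) and CLEC10A (1.0) not passing. PSMB9 (0.43) and TAP1 (0.42) rose among 10 class I genes, with HLA-B at 0.23 and TAPBP at 0.26. CD74 (0.31), HLA-DPA1 (0.32) and HLA-DRA (0.30) rose among 7 class II genes, with HLA-DPB1 at 0.29. The haemoglobin genes HBA1, HBA2 and HBB of red blood cells rose by 1.36, 1.0 and 1.26 but in 3, 2 and 2 of 4 sections. Without UPS 2 these values also moved by more than 1.5 times and did not pass: CXCL9 (0.70), NKG7 (0.45), LTB (0.35), IRF8 (0.40), PSMB9 (0.23), HLA-DPA1 (0.21), HLA-DRA (0.20) and HBA1 (0.56).

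Camera called 16 lists in T cell regions at the preset correlation, and none with an estimated correlation, where 11 lists had an unadjusted p under 0.05. Higher lists were plasma cell (adjusted p = 4.28e-25), class I (1.45e-14), cytotoxic lymphocyte (1.45e-14), class II (9.47e-14), lymphoid aggregate chemokine (3.41e-11), erythrocyte (3.72e-11), macrophage (2.56e-10), interferon response (6.57e-10), skeletal muscle (1.88e-08), checkpoint (2.09e-08), dendritic cell (5.67e-06) and adipocyte (0.0235). With an estimated correlation the adjusted p was 0.0537 for plasma cell, cytotoxic, dendritic, skeletal muscle, erythrocyte, interferon, checkpoint and chemokine lists, 0.0905 for class II, 0.0914 for macrophage, 0.109 for class I and 0.403 for adipocyte genes. Lower lists were fibroblast and matrix (1.61e-13, adjusted p = 0.130 with an estimated correlation), TGF-beta response (1.16e-05, 0.140 estimated), smooth muscle (0.00396, 0.289 estimated) and matrix remodelling enzyme (0.0495, 0.198 estimated), although MMP9 of the last list rose by 0.97 (0.25 without UPS 2, not passing). Members with the smallest p were AIF1 (0.36), C1QB (0.23), CD14 (0.26) and C1QC (0.25) for macrophages and PDGFRA (-0.33), COL6A3 (-0.20), FN1 (-0.15) and COL3A1 (-0.14) for matrix. None of these passed among all genes. The same held for TGFB1 (-0.33), TGFBI (-0.18) and THBS1 (-0.22) of TGF-beta response and LMOD1 (-0.31), SMTN (-0.19), TAGLN (-0.18) and ACTG2 (-0.20) of smooth muscle. It also held for ADAM12 (-0.26), LOX (-0.22) and MMP14 (-0.18) of remodelling and CFD (0.22), LPL (0.58), PLIN4 (-0.24) and CIDEC (0.42) of adipocytes. MYH7, the slow skeletal muscle myosin, rose by 0.59, with MYH1 (0.40), TNNT1 (0.38) and TNNC2 (0.29) not passing. The skeletal muscle call rests on UPS 2, where the list made 11205 CPM against 30.8 to 52.3 CPM elsewhere and had a median of 0.20, while the medians in LMS 1, UPS 1 and UPS 3 were -0.45, -0.23 and -1.03.

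edgeR called 94 of 12807 genes in T cell regions, 87 higher and 7 lower. DESeq2 called 0, with 206 at an unadjusted p under 0.05, and edgeR called 4 without UPS 2 and 52 without UPS 1. Of the 18 named genes, 1 passed without UPS 2, 8 without UPS 1, 16 without LMS 1 and 16 without UPS 3. List calls were lost for plasma cell, fibroblast and matrix (adjusted p = 0.0573), TGF-beta response (0.274), adipocyte (0.0646) and matrix remodelling enzyme genes (0.655) without UPS 2. They were also lost for smooth muscle genes without LMS 1 (0.380), adipocyte genes without UPS 3 (0.0789), and remodelling enzymes without UPS 1 (0.0776) or UPS 3 (0.121). Without UPS 2 the median of lymphoid aggregate chemokines went from 1.29 to 0.37 and that of cytotoxic genes from 0.82 to 0.46, and without UPS 1 that of fibroblast and matrix genes from -0.11 to -0.02, all still called. In LMS 1 only 2 of the 15 T cell genes were detected in 1% of spots, so its T cell regions rest on those 2 genes. The 250 spots of that region held 537760 UMIs, of which the whole T cell list made 260 CPM, fewer list UMIs than spots. Part of the region was therefore filled with spots without a count of those genes, tied at the lowest score, whose choice was arbitrary.

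In macrophage regions, genes of class II antigen presentation rose. HLA-DRA rose by a log2 fold change of 0.65 ± 0.12, CD74, the class II invariant chain, by 0.57 ± 0.11, HLA-DPA1 by 0.55 ± 0.13 and HLA-DPB1 by 0.53 ± 0.12 (SE, n = 4), each in all 4 sections, and 5 of the 7 class II genes passed. Without UPS 1 edgeR called 4 genes in all, so fewer than 5 class II genes passed there. C3AR1, the complement C3a receptor (ENSG00000171860, chromosome 12, 8056844 to 8066359), rose by 0.95 ± 0.19, CD209, a lectin of macrophages and dendritic cells, by 0.84 ± 0.20, CYBB, the phagocyte oxidase subunit, by 0.75 ± 0.18, and PTPRC, the leukocyte antigen CD45, by 0.74 ± 0.16. IGLC1 (1.31), ADAP2 (0.96), HLA-DOA (0.85), PLEK (0.82), the matrix protein TNXB (0.75), the monocyte attractant CCL2 (0.72), CYTH4 (0.71) and LAPTM5 (0.70) also rose in all 4 sections, while CENPP, a centromere protein (-1.11), and FSTL3 (-0.91) fell in all 4. TNXB stood at 2.73 in LMS 1 but 0.10, 0.33 and 0.05 in UPS 1, UPS 2 and UPS 3, and CYTH4 at 0.04 in UPS 3. Without LMS 1, TNXB (0.23, adjusted p = 0.663), CCL2 (0.46, 0.152) and CYBB (0.58, 0.0819) did not pass, while HLA-DRA (0.43) and LAPTM5 (0.47) did. IGLC1 stood at 0.77 without UPS 1 and FSTL3 at -0.59 without UPS 3, neither passing. CXCL10 rose by 0.71 in 3 of 4 sections.

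edgeR called 42 of 12724 genes in macrophage regions, 40 higher and 2 lower, at adjusted p between 0.000262 for IGLC1 and 0.0425 for FSTL3 among those named. DESeq2 called 1, and edgeR called 4 without UPS 1, 8 without UPS 2, 18 without UPS 3 and 68 without LMS 1. Of the 14 named genes, 0 passed edgeR's test without UPS 1 (454 genes at an unadjusted p under 0.05), 2 without UPS 2, 2 without UPS 3 and 11 without LMS 1. Of 20 random lists of like expression, 10 chose spots that gave at least as many calls in both directions together, while 1 gave at least 40 higher (59, with the next at 11) and 19 at least 2 lower. Camera called 11 lists and, with an estimated correlation, none, where 6 had an unadjusted p under 0.05. These were class II (adjusted p = 1.67e-16, 0.146 with an estimated correlation), T cell (1.71e-10, 0.146), interferon response (2.30e-07, 0.146), cytotoxic lymphocyte (1.83e-06, 0.180), class I (1.83e-06, 0.30), checkpoint (2.04e-04, 0.180), lipid-handling macrophage (8.64e-04, 0.180) and mast cell genes (9.06e-04, 0.217), all higher. Smooth muscle (9.44e-05, 0.180), proliferation (0.0102, 0.241) and hypoxia genes (0.0235, 0.521) were lower. Without UPS 1 the hypoxia list had a median of 0.02 with 9 of 17 genes positive (adjusted p = 0.908) and proliferation lost its call (0.178). Hypoxia genes also lost it without UPS 3 (0.0671), and proliferation genes without UPS 2 (0.0513) or UPS 3 (0.0570). Without LMS 1 the lipid-handling list kept its call (0.0221), but its median went from 0.20 to 0.01 with 5 of 10 genes positive, and SPP1 (-0.29) and GPNMB (-0.05) turned. Fibroblast and matrix, TGF-beta response and matrix remodelling enzyme genes were not called over 4 sections. Their medians were positive in LMS 1 and negative in UPS 1 and UPS 2. TGF-beta response genes stood at 0.70, -0.42, -0.33 and -0.11 in LMS 1, UPS 1, UPS 2 and UPS 3. In the same order, remodelling enzymes stood at 0.66, -0.20, -0.16 and 0.64, and fibroblast and matrix genes at 1.37, -0.20, -0.19 and 0.18. Without UPS 1 the T cell median went from 0.43 to 0.25 and the class I median from 0.11 to 0.05, both still called. None of the following members passed among all genes: CD2 (0.65), CD3D (0.62), CD8A (0.53) and TRBC2 (0.37) of T cells, CTSW (1.02), GZMK (0.46), CST7 (0.56) and PRF1 (0.50) of cytotoxic cells. The same held for SPP1 (0.92), LIPA (0.40), CTSD (0.27) and GPNMB (0.25) of lipid handling and CXCL9 (0.46), IFI27 (0.33) and IFIT1 (0.70) of the interferon response. Class I members were HLA-B (0.27), HLA-C (0.30) and B2M (0.22), and checkpoint members HAVCR2 (0.72), IDO1 (0.78), LAG3 (0.47) and TIGIT (0.32), none past the test. Nor did these pass: TPSAB1 (0.65), TPSB2 (0.46) and HDC (0.34) of mast cells and TAGLN (-0.27), CNN1 (-0.32), ACTA2 (-0.20) and ACTG2 (-0.24) of smooth muscle. ENO1 (-0.28), ALDOA (-0.27), SLC2A1 (-0.42) and MIF (-0.20) of hypoxia and RRM2 (-0.44), CDK1 (-0.36), PLK1 (-0.34) and TOP2A (-0.20) of proliferation did not pass either. Adjusted over the list alone, 6 class II, 5 T cell, 5 interferon, 2 class I, 2 checkpoint and 2 lipid-handling genes were higher.

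In endothelial regions, genes that rose included PODXL, AQP1 and RGS5. PODXL, a surface sialomucin of vessel lining (ENSG00000128567, chromosome 7, 131500271 to 131556628), rose by a log2 fold change of 1.94 ± 0.19 (SE, n = 4; edgeR adjusted p = 1.10e-19), and AQP1, a water channel of small vessels (ENSG00000240583, chromosome 7, 30911853 to 30925516), by 1.31 ± 0.12 (adjusted p = 5.17e-22). RGS5, a pericyte regulator of G protein signalling, rose by 1.86 ± 0.20 and MCAM by 0.67 ± 0.12, both in all 4 sections, and NOTCH3 rose by 0.40 in 2 of 4. ID1 (1.62), ACKR1, the chemokine receptor of venules (1.59), CLEC14A (1.56), RAMP3 (1.55), CD34 (1.54), NOTCH4 (1.5), the vessel transcription factor SOX18 (1.5), SLC9A3R2 (1.41) and PCDH12 (1.31) rose in all 4 sections. The muscle enolase ENO3 (-0.72), MBNL1-AS1 (-0.72), the muscle myosin light chain MYL1 (-0.58), YBX3 (-0.43), MTRNR2L12 (-0.40), GAPDH (-0.32), S100A10 (-0.30) and the ferritin heavy chain FTH1 (-0.29) fell in all 4 sections. MYL1 stood at 0 CPM in the regions of LMS 1 and UPS 3, against 0.43 and 2.32 CPM in the rest. ENO3 in UPS 3 stood at 0 against 2.32 CPM, so these falls rest on almost no counts.

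edgeR called 139 of 12934 genes in endothelial regions, 116 higher and 23 lower, against 20 by DESeq2 and 43 by edgeR without UPS 2. Of 20 random lists of like expression, 0 gave at least 116 higher and 6 at least 23 lower. Of the 20 named genes, 10 of 19 tested passed without UPS 2, 14 without UPS 1, 18 without LMS 1 and 20 without UPS 3. In UPS 3 the direction of 9 of the 20 rests on fewer than 10 UMIs, as does that of 3 in UPS 1 and 1 in LMS 1. Camera called 6 lists and, with an estimated correlation, none, where 4 had an unadjusted p under 0.05. The pericyte list was higher (adjusted p = 8.71e-09, 0.171 with an estimated correlation; 3 of 9 members rose, and 4 adjusted over the list alone; COX4I2 stood at 1.40 without passing). Without UPS 2 NOTCH3 (0.09) and MCAM (0.43) did not pass. The plasma cell list was higher (8.62e-06, 0.329 with an estimated correlation), with IGHM up by 1.66 in 3 of 4 sections, IGKC by 0.99 in 4 and IGLC2 by 0.73 in 2, and IGHG1 at 0.34 without passing. IGLC2 turned without UPS 3 (-0.19) and in the top 10% of spots (-0.49), and IGHM did not pass without UPS 3 (0.88). Without UPS 2 the list median went from 0.34 to 1.32, IGKC to 1.59 and IGLC2 to 2.56. TGF-beta response genes were higher (6.81e-04, 0.557 with an estimated correlation), with CCN2 up by 0.34 and CCN1 (0.34) and THBS1 (0.30) not passing. Without LMS 1 the median of this list went from 0.22 to 0.05 and its call was lost (adjusted p = 0.121), with CCN2 at 0.15. Skeletal muscle genes were lower (4.80e-21, 0.177 with an estimated correlation), with 5 of 12 members past the test, among them MYH2 (-0.79), MYH1 (-0.75) and CKM (-0.56, but 0.33 by DESeq2), and 9 adjusted over the list alone. These genes came almost wholly from UPS 2, where the list made 11205 CPM against 30.8 to 52.3 CPM elsewhere. Hypoxia genes (6.81e-04, 0.177 with an estimated correlation) and smooth muscle genes (0.00131, 0.177) were lower, with ALDOA down by -0.45 and CA9 (-0.97), LDHA (-0.19), PGK1 (-0.19), DES (-0.47) and TPM2 (-0.23) not passing, while TAGLN (0.30) and ACTA2 (0.26) lay on the other side of 0. No smooth muscle gene passed edgeR's test among all genes, and without LMS 1 the list turned, with a median of 0.07 and 9 of 13 genes positive (higher, adjusted p = 0.0310).

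Few genes were called in hypoxia regions, which the choosing list itself set apart only weakly. The hypoxia list made 6461 CPM in the region and 4420 in the rest of LMS 1, and 5732 and 3822 in UPS 1. In UPS 2 it made 3230 and 2029, and in UPS 3 6886 and 4510. This contrast was smaller than that of the other choosing lists in each section, so few calls say little about hypoxic tissue. NDUFA4L2, a hypoxia-inducible mitochondrial protein (ENSG00000185633), rose by a log2 fold change of 0.54 ± 0.10 (SE, n = 4; edgeR adjusted p = 6.57e-04), and SELENOP, a selenium transport protein (ENSG00000250722, chromosome 5, 42799880 to 42811892), fell by 0.34 ± 0.07 (adjusted p = 0.00501), both in all 4 sections, as the rule that named them asked. SPP1, the secreted phosphoprotein osteopontin, rose by 1.08 ± 0.14, but in 3 of 4 sections. The test called 8 of 12794 genes, 5 higher and 3 lower, DESeq2 called 0 with 73 at an unadjusted p under 0.05, and edgeR called 3 without UPS 1 and 16 without UPS 3. Neither NDUFA4L2 nor SELENOP passed without UPS 1. Of 20 random lists of like expression, 15 gave at least as many calls, and 7 at least as many higher.

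Camera called 12 lists in hypoxia regions and, with an estimated correlation, none, where 3 had an unadjusted p under 0.05. Skeletal muscle genes were higher (adjusted p = 4.50e-36, 0.112 with an estimated correlation), with MYH2 (0.47), MYL1 (0.43), ACTA1 (0.40) and MYLPF (0.42) not passing among all genes and 10 of 12 higher adjusted over the list alone. The list came almost wholly from UPS 2, and without ALDOA, ENO1, LDHA and PGK1 in the score its median went from 0.38 to -0.13 in UPS 2 and from 0.18 to -0.16 in UPS 1. TGF-beta response (7.32e-04), lipid-handling macrophage (0.0375) and proliferation genes (0.0375) were higher, with adjusted p = 0.284, 0.284 and 0.493 with an estimated correlation. Without UPS 1 the proliferation list had a median of -0.05 with 7 of 16 genes positive (adjusted p = 0.897), and without UPS 2 its call was lost (0.0991). Without UPS 2 the TGF-beta median went from 0.16 to 0.03, and lipid-handling genes lost their call without LMS 1 (0.136) or UPS 1 (0.189). SPP1 aside, their members TGFBI (0.27), TGFB1 (0.27), CCN1 (0.28), TREM2 (0.46), CD9 (0.19), APOC1 (-0.15), TYMS (0.24), BIRC5 (0.24), CDK1 (0.21) and MCM2 (-0.24) did not pass. Lower lists were class II (0.00434), T cell (0.00768), macrophage (0.00768), matrix remodelling enzyme (0.0121), erythrocyte (0.0263), interferon response (0.0263), endothelial (0.0451) and class I genes (0.0451). Each had an adjusted p between 0.284 and 0.493 with an estimated correlation. Of these 8 lists class II alone was called without each section in turn, while T cell and macrophage genes lost their call without UPS 1 (0.519 and 0.0523). None of their leading members passed. Class II members were CD74 (-0.14), HLA-DMB (-0.20), HLA-DPA1 (-0.13) and HLA-DRA (-0.10), and T cell members TRBC1 (-0.41), CD8B (-0.67), CD27 (-0.44) and CD5 (-0.69). Macrophage members were C1QB (-0.23), C1QA (-0.15), CD163 (-0.23) and MSR1 (0.29), and remodelling members MMP9 (-0.88), CTSK (-0.20), MMP14 (-0.17) and MMP11 (-0.22). Haemoglobin genes were HBA1 (-0.78), HBB (-0.61) and HBA2 (-0.25), and interferon response members IFI27 (-0.25), IFIT1 (-0.73), CXCL10 (-0.38) and CXCL9 (-0.32). Endothelial members were EGFL7 (-0.34), PLVAP (-0.29), ROBO4 (-0.62) and FLT1 (-0.49), and class I members B2M (-0.10), PSMB9 (-0.12), HLA-C (-0.08) and HLA-B (-0.06).

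**Figure D3:**
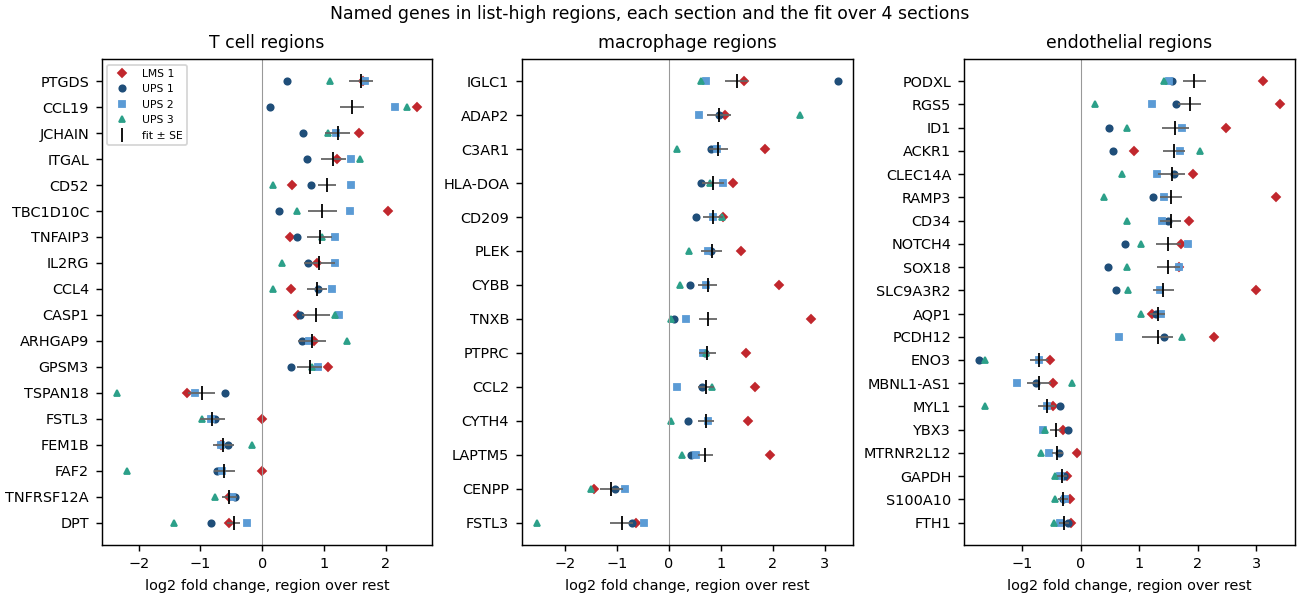
Log2 fold change of the named genes in T cell, macrophage and endothelial regions over the rest of the tissue, with 1 coloured point per section and a black tick with a bar for the fit over 4 sections ± SE. The rule that named these genes asked for 1 direction in all 4 sections, so their shared direction is no result, and the points of 1 gene spread widely, as for CCL19 in T cell regions from 0.13 in UPS 1 to 2.51 in LMS 1, the latter on 3 UMIs.

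Gene lists also shared spots. Macrophage genes and class II genes were found in the same spots in every section, with a rank correlation across spots, after removing depth, of 0.295 ± 0.0816 (mean and SD, n = 4). Fibroblast and matrix genes accompanied TGF-beta response genes (0.246 ± 0.155) and matrix remodelling enzymes (0.182 ± 0.163), and class I accompanied class II genes (0.193 ± 0.110). Macrophage genes also accompanied class I (0.156 ± 0.114), interferon response (0.132 ± 0.0568) and lipid-handling genes (0.131 ± 0.0514), and the interferon response accompanied class II genes (0.140 ± 0.0246). Of 91 pairs that could be scored in all 4 sections, 28 had the same sign in each, all positive, where 11.4 are given by chance for independent signs. Without UPS 2 the pair of fibroblast and matrix with remodelling enzymes stood at 0.106, and macrophage with lipid-handling genes did not share 1 sign across sections when the second list was read in neighbouring spots (mean 0.0858). Each of the 8 pairs above lay at percentile 100 of 1000 random lists of like expression. These pairs were picked for their high means, and other pairs, such as interferon response with class I genes, also lay there. The percentile therefore does not set the 8 pairs apart. The smallest two-sided exact sign-flip p that 4 sections allow lies above 0.05, so no pair could pass. Without removing depth 80 pairs had 1 sign.

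**Figure D4:**
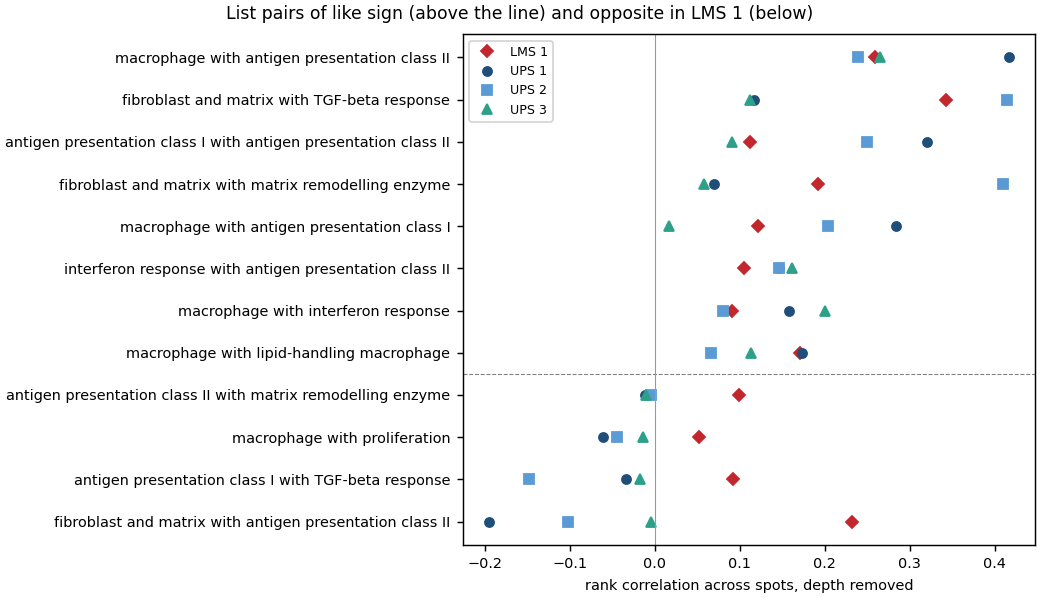
Rank correlation of list scores across the kept spots of each section, with depth removed and 1 point per section. Above the dashed line are the 8 pairs with the highest mean among those of like sign, led by macrophage with class II genes (0.239 to 0.416), and below it are pairs whose sign in LMS 1 is opposite to every UPS section.

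COL1A1, LUM, FTH1 and MTRNR2L12 were among the 100 genes of highest spatial correlation in every section. COL1A1, the main chain of type I collagen (ENSG00000108821, chromosome 17, 50184101 to 50201631), had a Moran's I, the correlation of a spot with its neighbours, of 0.171 in LMS 1, 0.13 in UPS 1, 0.746 in UPS 2 and 0.134 in UPS 3. LUM (0.229 ± 0.107), FTH1 (0.197 ± 0.0371) and MTRNR2L12 (0.292 ± 0.205; mean and SD, n = 4) were the other named genes, and FTH1 encodes the ferritin heavy chain. Across 4005 genes detected in 5% of spots of each section, 7 were shared, the other 3 of them mitochondrial, where random rankings give 0.00156, and 21 were shared without UPS 3. Random rankings treat all genes alike whatever their expression, so this comparison could not tell shared spatial structure from shared abundance. Each of the 4 named genes left the shared set under some alternative: COL1A1, LUM and MTRNR2L12 with Pearson residuals, LUM and MTRNR2L12 with 18 neighbours, and COL1A1, LUM and FTH1 at 1000 UMIs per spot. Leading genes differed by section: LUM, COL1A2, ALDOA, FOS and SFRP4 in LMS 1 (0.309 to 0.289), TGFBI, APOE, TIMP1, GAPDH and LDHA in UPS 1 (0.308 to 0.253), COL1A2, COL1A1, MTRNR2L12, SPARC and IGFBP5 in UPS 2 (0.749 to 0.545). In UPS 3 they were ENG, S100A6, CD9, SFRP4 and HSPA1A (0.276 to 0.218). In UPS 3 only 3 genes exceeded the highest value of shuffled spots, 0.225, against 334 in LMS 1, 281 in UPS 1 and 633 in UPS 2, so its ranking is close to noise, with a median of 2 kept neighbours per spot.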

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

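The tests of the UMIs outside the tissue and of the 3 genes found there were chosen only after the results were seen, while those of spot depth, tissue edge and smooth muscle genes in macrophage regions were written before. Differences between LMS and UPS rest on the single LMS section, and tumour type, which the design names, stays open and untested for each of them. In each interaction test the region effect of LMS 1 was fitted exactly and the spread came from the UPS sections alone. The counts below therefore say how far LMS 1 lay from those sections and show no difference between tumour types. Genes given there as higher or lower in LMS 1 had a higher or lower region effect, the log2 fold change of region over rest. This says nothing about their expression level in the whole section.

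Macrophage regions carried matrix genes in LMS 1 and not in 2 of the 3 UPS sections. An interaction test in edgeR called 123 of 13539 genes between LMS 1 and the UPS sections, 121 of them higher in LMS 1, among them SFRP4 (log2 difference 3.31), DCN (2.54) and LUM (2.25), both small proteoglycans of collagen fibres, S100A4 (2.65), TNXB (2.5), LAPTM5 (1.48) and CCL2 (1.20). The median log2 fold change of the fibroblast and matrix list in macrophage regions was 1.37 in LMS 1, -0.20 in UPS 1, -0.19 in UPS 2 and 0.18 in UPS 3. The regions were set apart more sharply in LMS 1, where the macrophage list made 1768 CPM in the region and 263 in the rest. In UPS 1, UPS 2 and UPS 3 it made 6937 against 3516, 4978 against 2436 and 7859 against 4580. Larger region effects in LMS 1 may follow in part from this sharper contrast, which was not tested.

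Spot depth and the tissue edge were argued against as the whole explanation of the macrophage and matrix pattern. Among spots with at least 1000 UMIs the correlation of the 2 lists was 0.292 in LMS 1, with the highest UPS section at 0.0430, and among spots at least 2 rings inside the tissue it was 0.213, with the highest UPS section at 0.0645. A hypothesis that macrophages in LMS may lie in a stroma set apart from smooth muscle tumour cells stays open: the smooth muscle list had a median of -0.22 in macrophage regions of LMS 1, just above the lowest UPS section at -0.22, where the test had asked for a lower value. The 95% interval of that difference, from resampling the genes of the list and added after the value was seen, ran from -0.38 to 0.70, too wide to decide. Values that go with the hypothesis were the correlations of smooth muscle genes across spots, at -0.237 with macrophage genes in LMS 1 against -0.0181, -0.0768 and 0.0712 in UPS 1, UPS 2 and UPS 3, and at -0.307 with fibroblast and matrix genes against 0.0573, -0.0915 and 0.0319; these differences were not tested.

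Spots outside the marked tissue, which the comparisons use only where the tissue mask was ignored as an alternative, held 60.9% of the UMIs of UPS 3, 29.5% of LMS 1, 11.2% of UPS 1 and 8.30% of UPS 2. RNA spread from the tissue was argued against as the whole explanation in UPS 3, since the first outside ring held a median of 1259 UMIs (95% bootstrap interval 1117 to 1490) against 808 in the tissue spots at the edge. That interval resampled the ring spots of 1 section as if independent and took the edge median as fixed, so it may be too narrow. A tissue mask that leaves out tissue could give this, with a ratio of ring to edge of 1.56 in UPS 3, but the ratio in LMS 1 was 1.03 as well, where the test had asked for less than 1 in the other sections, so this stays open. No biological explanation was tested.

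PLCG2 (ENSG00000197943, chromosome 16, 81739041 to 81962685), MTRNR2L12 (ENSG00000269028, chromosome 3, 96617186 to 96618223) and MTRNR2L8 were picked for their high share of counts outside the tissue, where the median gene with at least 200 counts had 28.1% in LMS 1, 10.1% in UPS 1, 7.80% in UPS 2 and 60.5% in UPS 3. A signal of the array itself that tissue covers was argued against as the whole explanation, since it would be level wherever the array is bare. Counts of the 3 genes together, most of them MTRNR2L12, went from 238, 563, 314 and 376 per 100 spots in the first outside ring of LMS 1, UPS 1, UPS 2 and UPS 3 to 48.6, 48.5, 43.4 and 43.3 more than 5 rings away. The ratio of far to first ring was highest in LMS 1, at 0.204 (95% bootstrap interval 0.165 to 0.257). Intervals of these ratios resampled spots as if independent and may be too narrow. Tissue itself held 51.4, 50.9, 246 and 35.9 per 100 spots. Spread of RNA from tissue could not be told apart, because the ratio of far to first ring for the 3 genes over that for all UMIs lay above 1 in LMS 1 (1.78), UPS 1 (1.54) and UPS 3 (5.19) but below 1 in UPS 2 (0.768, interval 0.634 to 0.922). PLCG2 alone was higher far from tissue in LMS 1 (0.0890 against 0.0285 per spot) and UPS 1 (0.0858 against 0.0516), and lower in UPS 2 (0.0457 against 0.133) and UPS 3 (0.0702 against 0.0781). Total UMIs per far spot were 12%, 2.22%, 3.98% and 7.08% of tissue in LMS 1, UPS 1, UPS 2 and UPS 3. Reads shared with the mitochondrial gene were not tested for MTRNR2L12 and MTRNR2L8, and no biological explanation was tested.

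The other interaction tests are given as values, each a log2 difference of the region effect, LMS minus UPS, and not of expression levels. In hypoxia regions 6 of 13611 genes were called, among them COMP (-3.53), TIMP3 (-1.51), DCN (-1.25), LUM (-1.22) and COL1A1 (-0.74), all lower in LMS 1. In T cell regions 2 of 13600 genes were called, POSTN (1.20) and CYFIP2 (-1.42), both named after their values were seen, but the T cell regions of LMS 1 were chosen on 2 detected genes against 15 in each UPS section and are unlike those of UPS. In endothelial regions 38 of 13932 genes were called, 32 higher in LMS 1, among them RGS5 (2.17) and SLC9A3R2 (2.12), and MYH11 was lower (-2.31).

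In 9 pairs of lists the correlation across spots had one sign in LMS 1 and the other in each UPS section, a difference that was not tested. Fibroblast and matrix with class II genes stood at 0.232 in LMS 1 against -0.101 ± 0.0952 in UPS (SD, n = 3), class II with matrix remodelling enzymes at 0.0995 against -0.00882 ± 0.00414, class I with TGF-beta response at 0.0920 against -0.0665 ± 0.0710, and class I with matrix remodelling enzymes at 0.0469 against -0.0390 ± 0.0451. Macrophage with proliferation genes stood at 0.0517 against -0.0401 ± 0.0237, macrophage with hypoxia at 0.0113 against -0.0575 ± 0.0540, and pericyte with interferon response at 0.0206 against -0.0171 ± 0.00880. Pericyte with smooth muscle genes stood at -0.00993 against 0.0622 ± 0.0183 and smooth muscle with hypoxia at -0.000616 against 0.0555 ± 0.0250.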

How the results depend on the processing

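Alternatives on the tissue mask, on spots inside the edge and on lists with a section left out were chosen after seeing the data. For named genes in the LMS against UPS test, 694 of 799 values kept direction and side of the threshold and 105 passed it, with none reversed; for T cell, macrophage, endothelial and hypoxia regions 824 of 1077, 644 of 785, 448 of 575 and 629 of 672 were kept, and 8, 6, 6 and 11 reversed. LMS against UPS gave 343 genes by DESeq2, 291 with no filter on low genes, 76 from spots inside the tissue edge and 0 to 170 without 1 UPS section; lists called were 0 with an estimated correlation and 12 to 22 without 1 UPS section. The median log2 fold change of all genes was -0.10 with TMM and 0.00 with library size only.

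Hypoxia regions gave 17 genes with RLE, 0 with DESeq2 (73 at unadjusted p under 0.05, against 532 by edgeR), 4 with the top 10% of spots, 5 with no depth balance, 16 with list share as score, 0 with no section block (0 at unadjusted p under 0.05), 15 with the tissue mask ignored and 3 to 16 without 1 section. T cell regions gave 0 with DESeq2 (206 unadjusted), 0 with no section block (3 unadjusted) and 4 to 118 without 1 section; macrophage regions 1 with DESeq2, 0 with no section block (2 unadjusted) and 4 to 68 without 1 section; endothelial regions 20 with DESeq2, 91 with the top 10% of spots, 0 with no section block (23 unadjusted) and 43 to 155 without 1 section. With an estimated correlation 0 lists were called in hypoxia, T cell, macrophage and endothelial regions, and without 1 section 6 to 9, 10 to 15, 9 to 14 and 6 to 7. Pairs of like sign were 80 with no depth adjustment and 34 to 77 without 1 section, where 3 sections must share a sign and up to 210 pairs could be scored. Of 80 values of the 8 named pairs 8 moved by more than their spread, all higher: 6 with no depth adjustment (0.229 to 0.386), macrophage with class I by list share (0.279) and interferon response with class II at 1000 UMIs (0.167). Shared spatial genes were 8 to 21 without 1 section, with all 7 kept, 10 with Pearson residuals (4 of the 7 kept), 7 with 18 neighbours (5 kept), 5 at 1000 UMIs (4 kept) and 9 among genes detected in 10% of spots (7 kept).

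These log2 values reversed. In hypoxia regions: with list share as score CDK1 (-0.0561), HBB (0.533), MCM2 (0.0925), MMP11 (0.10) and MSR1 (-0.0810); at 1000 UMIs HBA1 (0.118) and HBA2 (0.144). HBA2 reversed in the top 10% of spots (0.0746), HBB with the mask ignored (0.194), and MMP11 in the top 30% (0.160) and with no depth balance (0.152). In T cell regions these were CFD in the top 10% (-0.0475), CIDEC with the mask ignored (-0.0566), IFITM1 with no block (-0.0123), and IGLC2 (-0.134) and TNNT1 (-0.280) with DESeq2. Without 1 section IGHG1 ran from -0.47 (without UPS 2) to 1.77, IGLC2 from -1.04 (without UPS 2) to 1.69, and PLIN4 from -0.69 to 0.0454 (without LMS 1). In macrophage regions HDC reversed in the top 30% (-0.316), with no depth balance (-0.0256), with list share (-0.0648) and with the mask ignored (-0.0609). Without 1 section GPNMB ran from -0.0482 (without LMS 1) to 0.49 and SPP1 from -0.29 (without LMS 1) to 1.80. In endothelial regions ACTA2 (-0.180) and TAGLN (-0.0507) reversed with no block, CKM with DESeq2 (0.327), and IGHG1 (-0.799) and IGLC2 (-0.486) in the top 10%. Without 1 section IGLC2 ran from -0.19 (without UPS 3) to 2.56. The cause was not tested.

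Depth limits UPS 3 most. No paired analysis was possible because the LMS and UPS sections share 1 replicate number, which pairs no samples.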

Other observations

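UPS 2 held skeletal muscle RNA. ACTA1, the skeletal muscle actin, stood at 2607 CPM in UPS 2 and at most 4.41 CPM elsewhere, CKM, the muscle creatine kinase, at 1388 against at most 8.46, and MYH7, the slow muscle myosin, at 287 against at most 0.679. The list made 11205 CPM in UPS 2 and 30.8, 52.3 and 36.3 CPM in LMS 1, UPS 1 and UPS 3, and did not pass between LMS and UPS (camera adjusted p = 0.0563). DES, a muscle intermediate filament protein named after its values were seen, stood at 676 CPM in UPS 2, 10.2 in LMS 1, 1.34 in UPS 1 and 0 in UPS 3. The acute phase genes SAA1 and SAA2 stood at 353 and 184 CPM in UPS 2, 19.2 and 10.5 in UPS 3, and 0.445 and 0.223 in UPS 1.

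The other lists that did not pass between LMS and UPS are given as CPM in LMS 1 against UPS (SD, n = 3). B cell genes stood at 7.87 against 15.1 ± 8.42 (camera adjusted p = 0.250), neutrophil genes at 32.9 against 83.3 ± 32.7 (0.0729), dendritic cell genes at 11.1 against 72.6 ± 29.7 (0.173), mast cell genes at 4.29 against 25.6 ± 27.3 (0.0530) and lipid-handling macrophage genes at 3748 against 3871 ± 2457 (0.371). Endothelial genes stood at 398 against 517 ± 365 (0.328), adipocyte genes at 175 against 648 ± 495 (0.671), erythrocyte genes at 3.22 against 120 ± 122 (0.361) and epithelial genes at 70.8 against 55.5 ± 82.2 (0.0530). Hypoxia genes stood at 4831 against 3834 ± 1412 (0.0593), proliferation genes at 823 against 1167 ± 804 (0.389), TGF-beta response genes at 1384 against 1991 ± 776 (0.137) and immediate early and heat shock genes at 1107 against 1166 ± 617 (0.671). Schwann cell genes, too few for the set test, stood at 2.86 against 8.52 ± 4.63.

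The tests of splits and random lists were chosen only after the counts were seen, while the test of muscle genes in hypoxia regions was written before. A hypothesis was that glycolytic members of the hypoxia list, which muscle also expresses, may have chosen muscle spots in UPS 2. Without ALDOA, ENO1, LDHA and PGK1 in the score, the median log2 fold change of the skeletal muscle list in hypoxia regions of UPS 2 was -0.13, against 0.38 with them, which is what the hypothesis asked for. In UPS 1 it went from 0.18 to -0.16, and in LMS 1 it stayed at 0.15.

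The section block leaves 8 splits of the region sums that part every section, too few for a share under 0.05. Only 1 of the 8, the real one, gave as many genes in each region test: 8 against 5 at most for hypoxia, 94 against 80 for T cell, 42 against 28 for macrophage and 139 against 113 for endothelial regions. Some of the other splits among the 8 swap region and rest in 1 section only and so keep most of the real grouping. Splits that part only 2 sections gave up to 16, 123, 67 and 138 genes for hypoxia, T cell, macrophage and endothelial regions. These exceeded the real count in all but endothelial regions, so the splits do not set the real counts apart. Random lists of like expression gave at least as many genes in 15 of 20 draws for hypoxia regions (median 51.5, highest 96), so any list of like expression could give such a count there. For macrophage regions 10 of 20 draws did so (median 40, highest 99), and for T cell regions (median 8.5, highest 55) and endothelial regions (median 13, highest 77) 0 of 20. Most calls of random lists were lower. Counting higher calls alone, at least as many came from 7 of 20 draws for hypoxia regions (5 higher, highest draw 13), 1 of 20 for macrophage regions (40 higher, highest draw 59), 0 of 20 for T cell regions (87 higher, highest draw 7) and 0 of 20 for endothelial regions (116 higher, highest draw 71). Whether the higher calls of macrophage regions stand apart from those of random lists could not be told from 1 draw of 20. Counting lower calls alone, at least as many came from 9 of 20 draws for T cell regions (7 lower, highest draw 50). The same held for 6 of 20 for endothelial regions (23 lower, highest draw 68), 17 for hypoxia regions and 19 for macrophage regions. The lower calls were thus not set apart from those of random lists in any of the regions.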
